A study of Homo sapiens with 4 samples.

How the data were processed

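MicroRNAs (miRNAs) were measured in embryoid bodies, the aggregates that human embryonic stem cells form in suspension when they begin to differentiate. Per the labels, the cells were of the established line BG01V and received 10 uM TBBD, an inhibitor of H3R17 methylation, or the solvent DMSO. TBBD was given for 48 h, and the compound was generally added between day 2 and day 4 of embryoid body formation. There were 2 arrays per group. Per the labels' protocols, total RNA was extracted with Trizol and 100 ng of it was dephosphorylated and ligated to a Cy3-labelled nucleotide, so each array has a single colour. Ligation labels any RNA with a free 3' end, fragments of other RNAs included. The labels also give each array a set, and each set holds 1 TBBD and 1 DMSO array. What the arrays of a set share is not given in the sources used here.

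Per the file headers, the scanner images were processed with Agilent Feature Extraction 10.5.1.1, and all 4 arrays lay on 1 slide and were read in 1 scan, so slide and scan could not be tested as batches. The deposited scanner files hold spot intensity on a linear scale, after subtraction of background and spatial detrending and with no scaling between arrays, per the file headers. The raw mean intensity and the local background intensity of each spot are also in the deposited files. The authors' series table holds log2 values. Of its 939 rows 933 were matched by name, and on every array a matched cell was nonzero exactly where the scanner file's gene-detected flag was set. For bright miRNAs a nonzero cell was the log2 of the file's total gene signal plus a constant, with a median of 3.32 on each array. A cell of 0 in that table stands for a miRNA not detected, and such cells were set to the floor. The formula behind its dim values was not worked out. The medians of its columns over all rows were 0 on every array, and the medians of nonzero cells were 6.93 and 6.75 for TBBD and 6.95 and 6.63 for DMSO. No centring or shift between arrays was found in it.

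Each array carried 15739 spots, of which 15024 were miRNA spots. They belonged to 2689 probes for 939 miRNA names, 851 human and 88 from viruses or other sources, with 16 spots per miRNA and 1 to 4 probes. Spots with an outlier flag were left out, which were 6.46% to 7.34% of the miRNA spots per array. No miRNA spot was saturated. The processed signal was averaged per probe and summed over the probes of a miRNA. This sum is called the unscaled signal, and it carries no floor beyond a signal of 1 before log2 was taken. The alternative with no scaling between arrays keeps a floor set as in the main values, so its differences can be smaller. It was divided by the array's 75th percentile over the 25 human miRNAs above background on all 4 arrays. The result was floored at 0.0977, the median over arrays of the 5th percentile of scaled values above background, and put on the log2 scale. With 25 miRNAs the percentile is the value of a single miRNA, miR-1915 and miR-367 on the TBBD arrays and miR-1308 and miR-21 on the DMSO arrays. A probe was above background where over 50% of its unflagged spots were marked well above background by the software, which per the file headers uses 13 times the background SD, and a miRNA was above background where 1 of its probes was. The 39 human miRNAs above background on both arrays of a group were tested. Values at the floor carry no order, and 13 of the 39 were at the floor on at least 1 array. For a miRNA below background on both arrays of 1 group, a bound was computed from the lowest signal above background on those arrays. It was under 1-fold for each of the 7 such miRNAs, so no fold is given for them. Fitted differences of these 7 appear only in the result for miR-92a, in list medians and counts and among the alternatives, and are no measure of a change. Of the 23 miRNAs with several bright probes, 4 had probes of opposite sign, and the median range between probes was 0.21 (log2).

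miRNA names are those of the array design. Of the 851 human names, a RefSeq gene table gave a gene symbol for 831 and a synonym for 4. The other 16 had no miRNA gene there, among them the 6 tested entries miR-720, miR-923, miR-1274a, miR-1274b, miR-1280 and miR-1308, which are known as fragments of ribosomal or transfer RNA that were later withdrawn as miRNAs. No genome was used.

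The groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. All 4 arrays entered the fit and the main design had no term for the set. Changes are TBBD minus DMSO on the log2 scale. SDs are over 2 arrays. miRNA lists with at least 3 tested members were tested with limma's camera, with a preset correlation of 0.01, and beside it with an estimated correlation and with fry, which asks whether a list's members move one way on balance. The 17 lists, the tests, the named miRNAs and all but 2 of the alternatives were fixed before the data were examined. The lists were the miR-17~92 cluster and its paralogs, the miR-302 cluster with miR-367, the cluster of miR-371, miR-372 and miR-373, the chromosome 19 cluster C19MC, the let-7 family, the 14q32 imprinted cluster, HOX-embedded miRNAs, lists for neural, astroglial, muscle and heart, endothelial, blood, endoderm and liver, epithelial and fibroblast miRNAs, a list for p53, hypoxia and stress, and a technical list of GC-rich array signals. The last holds miRNA names whose signal on such arrays often follows RNA quality or fragments that are not miRNAs. Its name is a label only: the GC content of its members was not computed, and miR-494 is also in the 14q32 list. Brightness was ranked by mean scaled log2 signal. Named were the miRNAs above background in the miR-17~92 list, up to 10 in each direction past the threshold or, failing that, changed by 1 (log2) and the same way in both sets, up to 4 tested members with the largest change in each list, and the 5 brightest human miRNAs. None qualified by size of change. Other names were chosen after their values were seen, and this is said where they appear. Counts per array were compared with an exact permutation test, two-sided, whose smallest possible p with 2 against 2 arrays is 0.333.

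The set numbers in the labels were taken to pair the arrays. Over the 39 tested miRNAs the deviations from the group means of the same-set arrays had a correlation of 0.770, and 26 had the same sign in both groups. A fit with the set as a replicate block was therefore run beside the main fit. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

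The steps were tested on simulated data with 39 miRNAs of the TBBD against DMSO comparison, 12 of them changed, in 100 simulations. With a low noise of SD 0.1, limma recovered 100% of 2-fold, 4-fold and 8-fold changes, with 4.91% false calls. With the noise observed on these arrays it recovered 30.8% of 2-fold, 47.5% of 4-fold and 62.3% of 8-fold changes, with 6.49% false calls. That noise was taken after flooring, and the simulated values had no floor. The 13 miRNAs at the floor on at least 1 array therefore had too little noise, and these recoveries can be too high. A list of 7 with every member shifted 2-fold was recovered by camera in 100% of simulations with SD 0.1. Of unshifted lists 3% had a p under 0.05 in camera. Camera was not run with the noise observed on these arrays, so its recovery there is not known. All noise was drawn independently for each miRNA, so lists whose members move together between arrays were not covered. The number of arrays limits the precision of every value.

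Alternatives changed the background correction (normexp with an offset of 50), the scaling, the summary over probes, the filter on dim miRNAs, the floor, the treatment of flagged spots, the pairing, the variance model, the source of the values, the features tested and the arrays included. Scaling to the hur control features and the deposited series table with no scaling were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.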

Results

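Signals of 851 human miRNAs were measured on 4 single-colour arrays of embryoid bodies from the human embryonic stem cell line BG01V. A pair of arrays held RNA of cultures given 10 uM TBBD for 48 h, and a pair held RNA of cultures given the solvent DMSO. TBBD, a plant polyphenol also known as ellagic acid, inhibits methylation of H3R17, a histone mark set by the methyltransferase CARM1. The comparison asks which miRNAs differ in differentiating stem cells when that inhibitor is present. Each group had 1 array in set 1 and 1 in set 2. On the TBBD arrays 26 and 33 human miRNAs were above background, and on the DMSO arrays 43 and 47. In all, 25 were above background on every array and 51 on at least 1. The brightest by mean scaled log2 signal over the 4 arrays were miR-923 at 2.88, miR-720 at 0.67, miR-21 at 0.51, miR-1246 at 0.38 and miR-302b at 0.30. By mean unscaled signal miR-1202, of the GC-rich list, came after miR-923, at 402.1 against 1459. miR-923, an entry now known as a ribosomal RNA fragment, held 21.1% and 26.2% of the human signal on the TBBD arrays and 17.4% and 24.2% on the DMSO arrays.

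The embryonic stem cell cluster of miR-302 and miR-367 gave clear signal with both treatments. Of its 10 entries on the array, 6 were above background, and the entries together held 18.0% and 8.19% of the human signal on the TBBD arrays and 21.5% and 5.22% on the DMSO arrays. The miR-17~92 cluster and its paralogs, which promote proliferation, held 4.15% and 4.46% with TBBD and 5.01% and 3.82% with DMSO, with 7 of 27 entries above background. No member of the let-7 family, whose mature forms accumulate as stem cells differentiate, was above background on any of the 4 arrays, out of 18 entries. The same held for 36 neural, 8 muscle and heart, 11 endoderm and liver and 11 epithelial entries. It also held for the 5 entries of the stem cell cluster of miR-371, miR-372 and miR-373 and the 45 entries of C19MC, a primate-specific cluster active in placenta. Of the 25 astroglial entries miR-23a and miR-27a were above background on at least 1 array, of the 13 blood entries miR-150*, of the 9 HOX-embedded entries miR-10a, and of the 63 entries of the 14q32 imprinted cluster miR-134 and miR-494. miR-27a, miR-150*, miR-10a and miR-134 were named after their values were seen. At this brightness a signal below background does not show that a miRNA is absent.

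No single miRNA passed the test between TBBD and DMSO. Of 39 tested miRNAs, 0 passed limma's adjusted threshold and the smallest adjusted p was 0.858. At an unadjusted p under 0.05 there was 1, miR-21, which is widely expressed and abundant in proliferating cells. Its scaled level was 0.84 ± 0.02 (SD, n = 2) with TBBD and 0.18 ± 0.25 (SD, n = 2) with DMSO. The log2 difference was 0.66 with an SE of 0.17, a fold of 1.58, and an adjusted p of 0.858 in limma. It was above DMSO in both sets, by 0.49 and 0.82, and miR-21 itself set the scale of 1 DMSO array. Without scaling the difference was -0.22. With the set as a block 0 miRNAs passed and 0 had an unadjusted p under 0.05, and the smallest adjusted p in limma was 0.818. By value 29 of the 39 were higher with TBBD and 9 lower after scaling, and the median change was 0.21. That median depends on the scaling, being -0.29 with median scaling, 0 with quantile normalization, -0.59 with none and 0.42 with scaling to control features. The medians of the tested lists are therefore also given below relative to the median of all tested miRNAs. The median SE of 0.42 was above the median absolute change of 0.24.

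Before scaling, most miRNAs were dimmer on the TBBD arrays. The unscaled signal was lower with TBBD in both sets for 31 of the 39 tested miRNAs, with a median log2 difference of -0.64. Unscaled values here and below carry no floor, whereas the alternative with no scaling keeps one, so its medians are nearer to 0. For 0 of them was it at least 2-fold lower in both sets. The 75th percentile signal was 141 ± 28.9 (SD, n = 2) with TBBD and 258 ± 29.3 (SD, n = 2) with DMSO, a ratio of 1.83. The median of the same 25 miRNAs differed less, at 79.3 and 70.8 on the TBBD arrays and 99.0 and 86.1 on the DMSO arrays. The number of miRNAs above background was 29.5 ± 4.95 (SD, n = 2) with TBBD and 45 ± 2.83 (SD, n = 2) with DMSO, a difference of -15.5 (exact permutation test, p = 0.333, the smallest this design can give). In all 7 tested miRNAs were above background on both DMSO arrays and on neither TBBD array, which were miR-15b, miR-19a, miR-23a, miR-92a, miR-363, miR-494 and miR-1228, and 0 the other way round. miR-15b, a regulator of the cell cycle, was named after its values were seen.

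**Figure D1:**
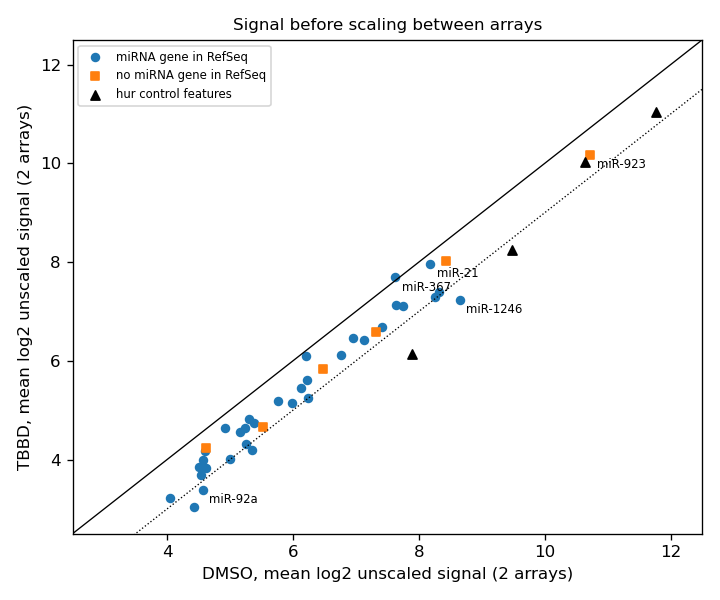
Mean log2 unscaled signal with DMSO (horizontal axis) and with TBBD (vertical axis) for the 39 tested miRNAs and 4 control features, each point a mean of 2 arrays. The solid line marks equal signal and the dotted line a log2 difference of -1; most points lie between them, with a median of -0.64 over the tested miRNAs. miR-92a, below background on both TBBD arrays, lies at the lower left.

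miR-92a, a member of the miR-17~92 cluster, was dim on these arrays. A test of its own was fixed before the data were examined, because the study is known to have followed miR-92a. The choice was therefore not independent of the study. Its unscaled signal was 10.6 ± 1.81 (SD, n = 2) with TBBD and 23.7 ± 0.571 (SD, n = 2) with DMSO, and it was lower with TBBD in both sets. It was above background on both DMSO arrays and on neither TBBD array, so no fold is given. After scaling, 3 of its 4 values were at the floor, so the fitted difference of -0.0039 (SE 0.073, adjusted p = 1 in limma) carries no information on its size. In the authors' deposited log2 values miR-92a was 5.50 ± 0.15 (SD, n = 2) with TBBD and 6.58 ± 0.038 (SD, n = 2) with DMSO, a difference of -1.09 in a table that follows the gene-detected flag and lists it as detected on all 4 arrays. That difference had an adjusted p of 0.0726 in limma without scaling and, at -0.84, an adjusted p of 0.359 with scaling. Over all alternatives the adjusted p of miR-92a ranged from 0.0726 to 1, and its scaled direction turned with normexp background correction, to 0.23. The offset of 50 added to every spot there is above its unscaled signal in both groups, so that turn is no measured rise.

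The 7 tested members of the miR-17~92 list differed little in value after scaling. By value 6 were above 0 and 1 below, with a median of 0.16 and a mean of 0.14, and the median was -0.67 before scaling and flooring, with 7 of 7 lower. Of the 7, 3 were below background on both TBBD arrays (miR-19a, miR-92a and miR-363), and their values are no measure of a change. Of the members, 0 passed the threshold over all miRNAs and 0 adjusted over the list alone (smallest adjusted p 0.291 in limma). miR-20a differed by 0.30 with an SE of 0.26, and by 0.058 without DMSO array 1, where the list median was also 0.058. miR-20b differed by 0.28 with an SE of 0.097, miR-19b by 0.21 with an SE of 0.079, and miR-17 by 0.026 with an SE of 0.12. The probes of miR-19b and of miR-17 had opposite signs, and with the mean of probe log2 values miR-19b was at 0.049, miR-20b at 0.16 and the list median at 0.046. miR-363, a paralog from the X-linked cluster, had unscaled means of 16.0 with TBBD and 24.3 with DMSO, and miR-19a had 13.2 and 23.3. The fitted log2 differences of all 7 were negative with no scaling and with median scaling. Relative to all tested miRNAs the list median was -0.049, and it lay between -0.16 and 0.011 over 6 scalings. Camera gave the list an adjusted p of 0.414, and 0.803 with an estimated correlation, and fry gave an adjusted p of 0.117. The camera call changed with the processing: the list passed as higher with normexp background correction (adjusted p = 0.041). That setting adds an offset of 50 to every spot before scaling, above the unscaled means of miR-19a, miR-92a and miR-363. Their values there follow the offset and the array scale, so this call is no measured rise of these members. With no filter on dim miRNAs camera gave an adjusted p of 0.00025, but 20 of the 27 entries then tested were never above background and the median was 0, so this is no measured rise. Camera called the list lower with no scaling (adjusted p = 0.019) and with the scaled deposited table (adjusted p = 0.011). With no scaling the list median was -0.58 and that of all tested miRNAs -0.59. No fall of the list beyond the other miRNAs was therefore measured there. In the scaled deposited table miR-19a was listed at 0 on TBBD array 1 and set to the floor. Over all alternatives the list's adjusted p in camera ranged from 0.00025 to 0.925.

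The miR-302 cluster, a mark of pluripotent cells, separated the sets rather than the treatments. After scaling, each of its 6 tested members was lower in set 2 than in set 1 in both groups, by a median of -1.13 with TBBD and -1.42 with DMSO, and 6 of 6 were lower there before scaling too. Between TBBD and DMSO the median was 0.10 and the mean 0.23, with 3 members above 0 and 3 below, 0 past the threshold and 0 adjusted over the list alone (smallest adjusted p 0.970 in limma). Within set 1 the median TBBD over DMSO log2 ratio was 0.049 and within set 2 it was 0.18. miR-367 had the highest value of the 39, at 0.94 with a 95% confidence interval from -2.80 to 4.68, with ratios of 0.37 in set 1 and 1.52 in set 2, and it stayed above the median of the tested miRNAs in all 6 scalings, but it was -0.20 without DMSO array 2. miR-302a differed by 0.40 with an SE of 0.77, miR-302c by 0.24 with an SE of 0.59, miR-302b by -0.037 with an SE of 0.90 and miR-302d by -0.11 with an SE of 1.02. Leaving out 1 array turned the sign of each of these members, miR-302a and miR-302c without TBBD array 1 or DMSO array 2, and miR-302b and miR-302d without TBBD array 2 or DMSO array 1. The probes of miR-302a and of miR-302b had opposite signs. Camera, which compares a list with the other miRNAs, gave the direction down with an adjusted p of 0.414, against the positive median and mean, and 0.803 with an estimated correlation. Relative to all tested miRNAs the median was -0.11, and it was below 0 in all 6 scalings, while the list median itself was negative with median scaling, quantile normalization and no scaling. With 1 array left out the list median ranged from -0.45 to 0.77, and the camera call changed with the array. The estimated correlation between members was 0.98, far above the preset of 0.01, so camera's p with the preset can be too small for this list.

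**Figure D2:**
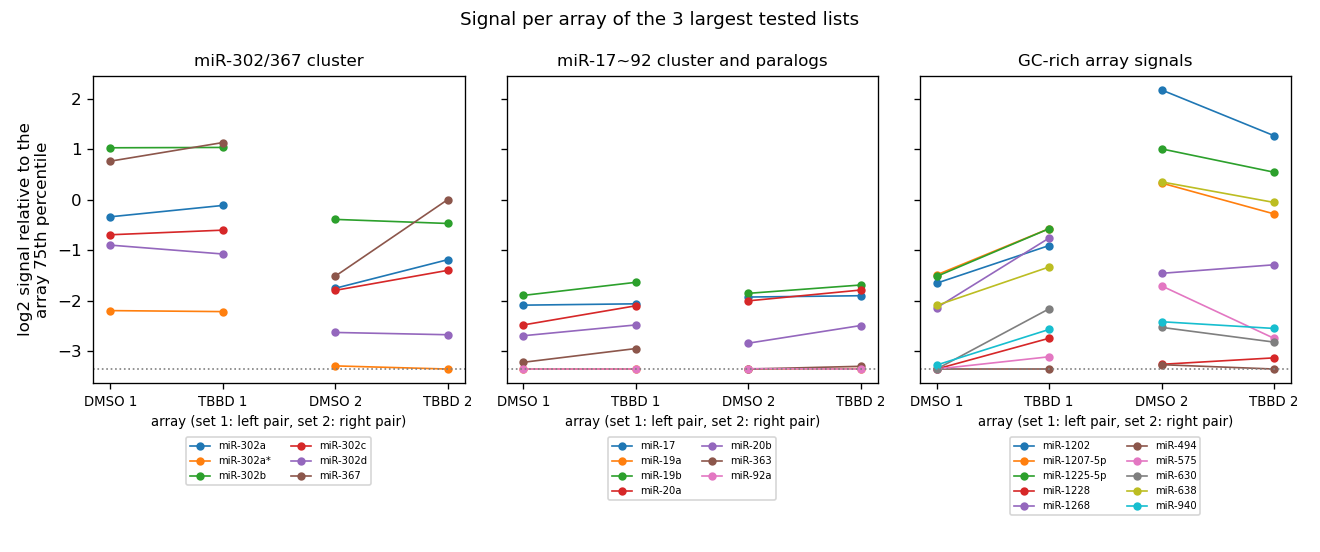
Scaled log2 signal (vertical axis) on each array for the tested members of the miR-302 list (6), the miR-17~92 list (7) and the GC-rich list (10), with lines joining the DMSO and TBBD arrays of a set and the dotted line at the floor of -3.36. The miR-302 members are lower in set 2 by a median of -1.13 (TBBD) and -1.42 (DMSO), and the GC-rich medians differ by 0.16 and 1.25, with 6 of 10 members higher in set 2 in both groups.

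The GC-rich list lay the other way between sets. Of its 10 tested members, 6 were higher in set 2 in both groups, and the median difference between sets was 0.16 with TBBD and 1.25 with DMSO. Between TBBD and DMSO the median was 0.21, with 7 above 0 and 3 below, but it was 0.75 in set 1 and -0.35 in set 2. Before scaling and flooring the list median was -0.67, with 10 of 10 lower. Relative to all tested miRNAs it was -0.0027, and it lay between -0.022 and 0.049 over 6 scalings. miR-1268 differed by 0.78 with an SE of 0.38, by 0.43 without DMSO array 1, and by -0.10 with no scaling. miR-630 differed by 0.45 with an SE of 0.46, and by 0.038 without DMSO array 1. miR-575 differed by -0.40 with an SE of 0.73, and ranged from -1.22 to 0.43 with an array left out. miR-1228 was below background on both TBBD arrays, with unscaled means of 18.2 for TBBD and 24.4 for DMSO, and no fold is given. miR-630 and miR-575 each had 1 value at the floor. Of the 10 members 0 passed the threshold and 0 adjusted over the list alone (smallest adjusted p 0.770 in limma). Camera gave the direction down, against the positive median, with an adjusted p of 0.521, and 0.803 with an estimated correlation. Camera's direction was down without DMSO array 1 and up without DMSO array 2. With 1 array left out the list median ranged from -0.45 to 0.96. The estimated correlation between members was 0.68, far above the preset of 0.01, so camera's p with the preset can be too small for this list too.

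Few miRNAs of other cell types or of stress could be compared. The 3 tested members of the p53, hypoxia and stress list were miR-21, miR-22 and miR-23a, with a median of 0.12 after scaling and -0.78 before scaling and flooring, an adjusted p of 0.414 in camera and 0.803 with an estimated correlation. Relative to all tested miRNAs the median was -0.091, and it lay between -0.18 and 0.37 over 6 scalings. With 1 array left out the scaled list median ranged from 0 to 0.30. With no filter on dim miRNAs camera gave an adjusted p of 0.039, with 14 of 18 entries never above background and a median of 0. miR-22, also on the fibroblast list with miR-21, differed by 0.12 with an SE of 0.18 and had 2 values at the floor. For the fibroblast list the smallest adjusted p over the list alone was 0.0759 in limma, for miR-21. miR-23a was at the floor on all 4 arrays and has no measured change. miR-424, on the endothelial list, differed by 0.42 with an SE of 0.69, and it was 1.25 higher in set 2 with TBBD and 1.00 higher with DMSO. It was above background on only 1 TBBD array, so its differences that involve TBBD are uncertain in size. Its difference was -0.34 with no scaling and ranged from -0.21 to 1.04 with an array left out. miR-494, from the 14q32 cluster, had 3 of 4 values at the floor, with unscaled means of 8.42 for TBBD and 21.7 for DMSO. Among the brightest entries miR-923 differed by 0.33 with an SE of 0.42, miR-720 by 0.49 with an SE of 0.52 and miR-1246 by -0.53 with an SE of 0.68. miR-1246, known as a fragment of a small nuclear RNA, had a ratio of 0.58 in set 1 and -1.63 in set 2. Its difference was -1.11 with median scaling and -1.41 unscaled, the lowest of the 39, and ranged from -1.15 to 0.088 with an array left out. miR-923 and miR-720 were negative with median scaling and with no scaling.

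Of the 39 tested miRNAs 0 differed 2-fold in the same direction in both sets, and 0 differed 1.5-fold. Set 2 against set 1 within each group gave 9 such 2-fold differences, 3 higher and 6 lower in set 2. In the authors' deposited values, with cells of 0 set to the floor, 9 of 63 tested miRNAs met the 2-fold criterion as lower with TBBD without scaling, and 5 with scaling. By the background criterion used here these entries do not give measured folds, although miR-33b*, miR-92a, miR-575, miR-1234 and miR-1238 were nonzero on all 4 arrays of that table. Of the 9, 8 were below background on both TBBD arrays by the criterion used here, 4 were listed at 0 on at least 1 TBBD array, and 0 were above background on both. Of the 5, 4 were below background on both TBBD arrays, and 5 were listed at 0 on at least 1. The 9 were miR-19a, miR-33b*, miR-92a, miR-191*, miR-365, miR-575, miR-1181, miR-1234 and miR-1238, and the 5 were miR-19a, miR-22, miR-191*, miR-365 and miR-1181. None of the 63 passed limma's adjusted threshold in either form, with 13 at an unadjusted p under 0.05 without scaling and 6 with it. miR-33b*, miR-191*, miR-365, miR-1181, miR-1234 and miR-1238 were named after their values were seen.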

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

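The test below was chosen after the result was seen. Among 6 features outside the comparison that were bright on both TBBD arrays, namely 5 control features and 1 viral miRNA probe, the control feature hur_1 was higher after scaling on both TBBD arrays than on both DMSO arrays, with a ratio of 1.21. Its scaled signals were 6.97 and 8.11 with TBBD and 5.77 and 6.73 with DMSO. The files do not say what it binds, and its unscaled log2 difference was -0.61. Only features higher with TBBD were looked for, and hur_4 was separated the other way, at 0.72 and 0.36 with TBBD and 0.88 and 0.98 with DMSO. With 2 against 2 arrays chance alone puts a feature in this order in 16.7% of cases. As 6 features were looked at, 1 such feature is no evidence of a change.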

How the results depend on the processing

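The count of 0 miRNAs past limma's adjusted threshold held in all 23 alternatives, with a smallest adjusted p of 0.0579 (scaled deposited table) and 14 miRNAs at an unadjusted p under 0.05 with normexp background. The count of 0 miRNAs changed 2-fold in both sets held in 19 of 21 alternatives, the exceptions being 9 with the deposited table as it stands and 5 with that table scaled, of which 8 and 4 were below background on both TBBD arrays. With the set as a replicate block the counts were 0 miRNAs, 0 lists and 0 at an unadjusted p under 0.05, with miR-92a at -0.0039, and the block changed no call and no direction. The difference in miRNAs above background was -15.5, and by the files' gene-detected flag it was -26.5. The count of lists called was 0. It became 1 with normexp, 1 with no scaling, 1 with the scaled deposited table and 2 with no filter on dim miRNAs. Without that filter most members of both lists were never above background. Camera calls also changed when an array was left out, which leaves 1 array in a group. Total gene signal, the mean of probe log2 values, either change of the floor, the variance trend, the limit to miRNAs above background on all 4 arrays and added non-human features changed no direction or call, though the mean of probe log2 values lowered miR-19b to 0.049, miR-20b to 0.16 and the miR-17~92 list median to 0.046. miR-92a was below background on the TBBD arrays, so it has no value under that limit. Slide as a block was not run, as there was 1 slide. The 2-fold count needs both sets and has no value with an array left out. Where an array was left out, its group's lone array was assumed to vary like the other group. The scaled floor limits 13 of the 39 miRNAs, which reached it on at least 1 array. It can lie above signals that were above background, as for miR-630, above background on all 4 arrays and at the floor on 1. Scaling to control features and the deposited table with no scaling were chosen after seeing the data.

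None of the single miRNAs below passed limma's adjusted threshold in any setting. The values that follow are log2 differences whose sign turned against the main fit. Those of miR-19a, miR-92a, miR-363, miR-494 and miR-1228, below background on both TBBD arrays, are fitted values and no measure of a change. With no scaling the values keep a floor. Scaling by another factor shifts all miRNAs of an array together by construction, and so turned signs under those scalings. Normexp adds an offset of 50 to every spot, above the unscaled means of miR-92a and miR-494 in both groups, so their turn there is no measured rise. For the other turns with normexp, and for quantile normalization, the flags and the deposited table, the cause was not tested. With normexp they were miR-92a 0.23, miR-302b 0.11, miR-302d 0.32, miR-494 0.19 and miR-575 0.21. With the percentile over all human miRNAs they were miR-302b 0.13 and miR-302d 0.057, and with scaling to control features miR-302b 0.17 and miR-302d 0.092. With median scaling they were miR-17 -0.55, miR-19a -0.060, miR-19b -0.37, miR-20a -0.28, miR-20b -0.30, miR-363 -0.16, miR-923 -0.25, miR-720 -0.092, miR-302a -0.18, miR-302c -0.33, miR-424 -0.031, miR-22 -0.014, miR-630 -0.034, miR-1228 -0.076, the miR-17~92 list median -0.28, the miR-302 cluster median -0.45 and the GC-rich median -0.31. With quantile normalization they were miR-17 -0.20, miR-19b -0.11, miR-363 -0.052, miR-302c -0.13, the miR-17~92 list median -0.031 and the miR-302 cluster median -0.17. With no scaling they were miR-17 -0.85, miR-19a -0.29, miR-19b -0.67, miR-20a -0.58, miR-20b -0.60, miR-363 -0.33, miR-923 -0.55, miR-720 -0.39, miR-21 -0.22, miR-302a -0.48, miR-302c -0.64, miR-424 -0.34, miR-22 -0.32, miR-1268 -0.10, miR-630 -0.29, miR-1228 -0.36, the miR-17~92 list median -0.58, the miR-302 cluster median -0.71, the stress list median -0.22 and the GC-rich median -0.62. By the gene-detected flag they were miR-17 -0.17, miR-19a -0.17, miR-22 -0.10, the miR-302 cluster median -0.10 and the GC-rich median -0.036, and with flagged spots kept miR-17 -0.019. In the scaled deposited table they were miR-17 -0.52, miR-19a -1.44, miR-19b -0.42, miR-20a -0.34, miR-20b -0.61, miR-363 -0.72, miR-923 -0.31, miR-720 -0.15, miR-302a -0.24, miR-302c -0.48, miR-424 -0.57, miR-22 -1.31, miR-630 -0.046, miR-1228 -0.18, the miR-17~92 list median -0.61, the miR-302 cluster median -0.56, the stress list median -0.39 and the GC-rich median -0.47. In that table with no scaling they were miR-17 -0.77, miR-19a -1.47, miR-19b -0.67, miR-20a -0.58, miR-20b -0.86, miR-363 -0.97, miR-923 -0.55, miR-720 -0.39, miR-21 -0.22, miR-302a -0.48, miR-302c -0.73, miR-424 -0.82, miR-22 -1.34, miR-1268 -0.10, miR-630 -0.29, miR-1228 -0.42, the miR-17~92 list median -0.86, the miR-302 cluster median -0.81, the stress list median -0.52 and the GC-rich median -0.66. With an array left out the values ranged, for miR-17 -0.054 to 0.11, miR-363 -0.013 to 0.34, miR-923 -0.14 to 0.79, miR-720 -0.11 to 1.08, miR-1246 -1.15 to 0.088, miR-302b -0.79 to 0.72, miR-367 -0.20 to 2.08, miR-302a -0.31 to 1.104, miR-302c -0.31 to 0.79, miR-302d -0.98 to 0.75, miR-424 -0.21 to 1.04, miR-22 -0.060 to 0.30, miR-575 -1.22 to 0.43, the miR-302 cluster median -0.45 to 0.77 and the GC-rich median -0.45 to 0.96. Without a turn of sign, miR-20a ranged from 0.058 to 0.54, miR-630 from 0.038 to 0.86, miR-1268 from 0.43 to 1.12 and the miR-17~92 list median from 0.058 to 0.14.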

Other observations

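All tests of explanations in this part were chosen after the results they bear on were seen, and so were the comparison of sets by limma and the names of the miRNAs it singles out.

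Among the splits of these arrays only the one by set gave calls, and these lay in the stem cell cluster. A limma fit of set 2 against set 1, each with 1 TBBD and 1 DMSO array, gave 3 calls out of 39, all lower in set 2, with 12 miRNAs at an unadjusted p under 0.05. They were miR-302b at -1.46, miR-302d at -1.66 and miR-302a* at -1.12, each with an adjusted p of 0.00782. miR-302a* was above background on only 1 TBBD array and its TBBD 2 value was at the floor, so the size of its difference is uncertain. With treatment added to that limma fit 0 passed, and the adjusted p of each of the 3 called miRNAs was 0.0852. The split by treatment gave 0 calls and 1 unadjusted, and so did TBBD 1 with DMSO 2 against TBBD 2 with DMSO 1. The arrays of a set correlated at 0.960 and 0.941 over the 39 miRNAs, against 0.865 for the TBBD arrays and 0.671 for the DMSO arrays, where miRNAs are not independent replicates.

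A first pattern is the lower unscaled signal with TBBD. A fall confined to miRNAs as a class would leave other small RNAs unchanged. The 6 tested entries with no miRNA gene in RefSeq were all lower on average too, with a median of -0.60 (range -0.86 to -0.38). This argues against it for these 6 entries, although in set 2 miR-720 and miR-1308 were higher with TBBD. The median was -0.65 for the 33 others (permutation test of the difference in medians, two-sided, p = 0.612, 100000 resamples). The 33 include miR-1246 and the GC-rich list, and entries of the same arrays are not independent. That p therefore does not show that miRNAs and other fragments fell alike. Lower brightness of the whole array remains a candidate explanation, since the 4 bright hur control features were also lower, with a median of -0.99 (range -1.75 to -0.61). What those features bind is not given, so less small RNA of every kind per ng of total RNA after TBBD stays open and was not tested.

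A second pattern is the split by set. Scaling cannot produce it, since the GC-rich median minus the miR-302 median, taken within each array, was higher in set 2 by 0.76 with TBBD and 2.38 with DMSO, on average 1.57. Probe signal that does not come from miRNA may lie behind the GC-rich part: the viral probe kshv-miR-K12-3 was above background on all 4 arrays and higher in set 2 by 0.50 with TBBD and 1.58 with DMSO. A second viral probe, hcmv-miR-UL70-3p, was above background on 1 array and at the floor on the others, and the mean over both probes was 0.58, so this explanation was neither excluded nor shown. The labels give no biological difference between the sets, so no biological explanation was tested, and a different stage of differentiation stays open.

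A further pattern is the lower unscaled miR-92a. The fall that other dim miRNAs share is a candidate explanation: of 8 other tested miRNAs with a DMSO signal between 15 and 30, all were lower by measured signal with TBBD, and 1, miR-494, by at least as much as miR-92a. The unscaled log2 difference was -1.17 for miR-92a, and the 8 had a median of -0.71 with an SD of 0.32 over the 8. Relative to the median of all tested miRNAs, miR-92a was at -0.53 unscaled. The 8 include miR-19a and miR-363 of the miR-17~92 list, so they are not all unrelated to miR-92a. Of these 8, 6 were below background on both TBBD arrays, as miR-92a was, so the sizes of these differences are not known and the order among them is uncertain. They were tested because they were above background with DMSO, which favours lower values with TBBD. An effect of TBBD on miR-92a beyond a shared fall stays open.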
